A study of Mus musculus with 4 samples.

How the data were processed

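The data were back-splice junction reads of circRNAs in 4 libraries of primary mouse articular chondrocytes, 2 with IL-1β and 2 controls. Per the labels' protocols, ribosomal RNA was removed, the RNA was digested with RNase R, which degrades linear RNA, and strand-specific libraries were made. The submitters' processing notes name the mm10 genome and Bowtie2. The circRNA caller, its filters and the handling of duplicate reads are not given in the sources used here. The authors deposited junction reads as whole-number counts for each circRNA and library, per the file headers. The authors also deposited SRPBM, a depth-scaled signal, per the file headers, and dividing the counts by it gave 1 constant per library (11.9, 13.4, 11.8 and 16.1 reads per SRPBM for IL-1β 1, IL-1β 2, control 1 and control 2). The control samples' labels carry the same treatment text as the others, so controls were taken from the source label.

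All 4 single-library tables held the same values as the series table. The series table lists 40909 circRNAs with numbers up to 41588. The other numbers were not analysed here. Linear gene expression was not analysed here, so the comparison of gene expression fixed beforehand was not run. Junction ends were placed in RefSeq genes of the same assembly (GRCm38.p6). A circRNA was given a host gene when both ends lay inside exactly 1 coding gene, or failing that exactly 1 other gene. The table used has no strand or exon positions, so exon or intron is not stated, and of hosts with at least 5 circRNAs 99.83% of circles lay on the host's majority strand. Only 451 circRNAs with a host lay inside further genes too. Circles that lay inside several coding genes made up 0.4% of circRNAs and 1.26% of reads.

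Counts were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, no covariate) for circRNAs or hosts with at least 20 reads over the libraries, with Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 change divided by the square root of F. Host output is the sum of junction reads over the circles of a gene. Gene lists with at least 5 tested hosts were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, and with fry. There were 19 lists, 13 of them tested, and 16 genes belong to more than 1 list. Folds against a group at 0 are lower bounds against 3 reads per library and cover counting error only. Python 3.11.15 with scipy 1.17.1 was used for the other values.

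The circRNAs and hosts named were set by a rule written before the data were examined: the 12 circRNAs and 10 hosts in each direction with the lowest p past the threshold, filled by the lowest unadjusted p where fewer passed, the 5 circRNAs with the highest mean level, and the 4 tested members of each list with the lowest p. Since 3 circRNAs and 0 hosts passed, nearly all named items come from the filling. Other circRNAs named as neighbours or for 0 reads in a library were chosen after their values were seen. Some list members that the rule picks are not reported here.

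The tests were run on simulated counts for the same 15333 circRNAs and 4879 hosts, with 200 changed. Each fold was simulated once, and the share of false calls depends on the number changed. For circRNAs edgeR recovered 0% of 2-fold and 7.5% of 4-fold changes (29.8% of those with at least 200 reads). For hosts it recovered 0% and 36.5%. DESeq2 1.42.0 recovered 0% of 2-fold circRNA changes and 7.5% of 2-fold host changes, with 25% of those host calls false. It recovered 9.5% of 4-fold circRNA changes and 35.5% of 4-fold host changes, with 64.8% and 20.2% of its calls false against 34.8% and 7.6% for edgeR. The coefficient of variation between libraries of a group was 118.5% for circRNAs and 71.4% for hosts, and 29.6% for hosts with at least 200 reads, so most 2-fold changes would be missed with this spread between libraries. By counting error alone, a count of 0 allows up to 3.35 and 3.06 CPM in the IL-1β libraries and 2.50 and 2.49 CPM in the controls.

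Alternatives fixed before the data were examined were a replicate block, DESeq2, RLE factors, library totals, other read filters, each library left out, depth taken from SRPBM, only circles inside 1 coding gene on the majority strand, and, for detection, other read minimums and thinning to 895774 reads. Added later were sums over junctions within 5 nt, a filter of 200 reads and robust empirical Bayes.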

Results

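Circular RNAs (circRNAs) were profiled in primary mouse articular chondrocytes, the cells that make and maintain joint cartilage, with and without interleukin-1β (IL-1β), an inflammatory cytokine used to model osteoarthritis in culture. A circRNA is a closed RNA loop made by back-splicing, and each was measured by the reads that cross its back-splice junction. There were 2 libraries from cells given recombinant human IL-1β at 10 ng/ml for 24 h and 2 control libraries. The IL-1β libraries held 895774 and 980542 junction reads, and the control libraries held 1198010 and 1203855. The labels do not say whether the 2 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Floors and bounds for counts of 0 cover counting error only, since reads amplified by PCR are not independent molecules. They also leave out circles missing from 1 library of a group: circRNA.20203 had 0 reads in control 1 and 9526 in control 2. Folds given as at least a value are therefore not limits on the true change.

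The cells yielded 40909 distinct circRNAs, of which 39571 (96.73%) were assigned to 1 host gene each, spread over 6930 host genes. The host gene with the most circRNAs was Arhgap10, a GTPase-activating protein, with 112. By junction reads the leading hosts were Nfix, a nuclear factor I transcription factor, with 139224 reads, Arhgap10 with 129089, the kinase gene Hipk3 with 50327, Utrn (utrophin, a relative of dystrophin) with 50002 and Setbp1 with 47861. The median distance between the ends of a junction was 10570 bp. Genome coordinates are in mm10.

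The first question was which circRNAs the cells held with and without IL-1β. The libraries held 18897 ± 1382 circRNAs each (SD, n = 4 libraries), with 17649 and 19317 in the IL-1β libraries and 20662 and 17960 in the controls. Only 6877 circRNAs (16.81%) were read in all 4 libraries, and these carried 84.95% of the junction reads. A further 23953 (58.55%) were read in 1 library only and carried 5.23% of the reads. There were 1004 circRNAs read in both IL-1β libraries and in neither control, and 1111 in both controls and in neither IL-1β library. The 4 pairs that mix the groups held 998.8 such circRNAs on average, between 673 and 1368, so presence and absence did not separate IL-1β from control beyond the spread between libraries. The 2 IL-1β libraries shared 36.8% of the circRNAs found in either, the 2 controls 34.44%, and pairs across the groups between 33.46% and 37.18%. Over 3100 circRNAs with at least 200 reads, log2 CPM correlated most between the IL-1β libraries (Pearson 0.812, Spearman 0.82). The controls had the lowest Pearson correlation of the 6 pairs, 0.684 (Spearman 0.737), against 0.694 to 0.757 across the groups (Spearman 0.721 to 0.764). Of circRNAs with 10 to 19 reads in a library, between 48.35% and 61.98% had 0 reads in the other library of the same group. With 200 or more reads this was between 0.51% and 1.36%.

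**Figure D1:**
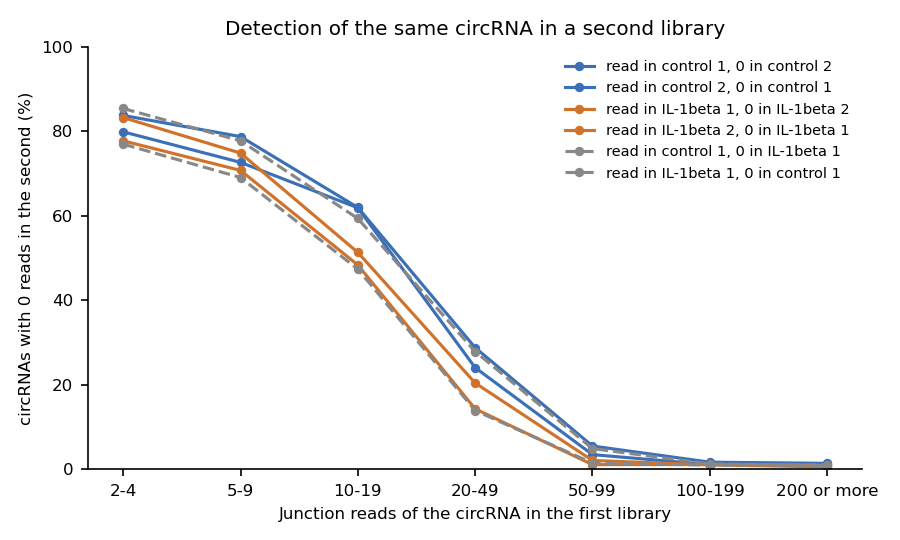
The share of circRNAs with 0 reads in a second library (y axis, percent) is plotted against the junction reads of the circRNA in the first (x axis, bins of reads), for both orders of each same-group pair (solid lines, blue for control and orange for IL-1β) and of 1 cross-group pair (dashed grey). Same-group and cross-group lines overlap, and at 10 to 19 reads the same-group lines lie between 48.35% and 61.98%.

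Of the 5 most abundant circRNAs, 4 had group means within 1.13-fold of each other and 1, from Setbp1, was 1.51-fold lower with IL-1β, and none passed edgeR's quasi-likelihood test. The most abundant of all, circRNA.37871 from Nfix (chromosome 8, 84771784 to 84772315, minus strand), stood at 27700 ± 117 CPM with IL-1β and 31100 ± 7440 CPM in control (mean ± SD, n = 2 each; CPM is normalised junction reads scaled to a common library total). The single-junction Hipk3 circle circRNA.20556 (chromosome 2, 104470749 to 104471847) stood at 11800 ± 688 and 11700 ± 1410 CPM, a log2 change of 0.01 ± 0.17 (SE) that was -0.20 when libraries were scaled by the depth behind the authors' SRPBM. For circRNA.37633 from Arhgap10 (chromosome 8, 77310731 to 77365160) the values were 9260 ± 576 and 9010 ± 150 CPM, a log2 change of 0.04 ± 0.16 that was -0.19 under the same scaling. The circle circRNA.17136 (chromosome 19, 4792398 to 4794009), which lies inside several overlapping coding genes, stood at 8600 ± 478 and 9310 ± 1080 CPM. The 3rd most abundant, circRNA.15856 from Setbp1 (chromosome 18, 79086551 to 79087180), had the largest difference of these, 7530 ± 727 CPM with IL-1β against 11300 ± 2680 in control, a log2 change of -0.59 ± 0.22 with an adjusted p of 0.886 in edgeR. Scaling by the SRPBM depth moved the median log2 change of all tested circRNAs from -0.05 to -0.28, so log2 changes here are relative to the bulk of circRNAs. Of circRNAs with an unadjusted p under 0.05, 280 were higher and 248 lower with TMM, against 123 and 347 with that scaling. Summed over circRNAs, SRPBM was 75093 and 73067 in IL-1β 1 and IL-1β 2, 101537 in control 1 and 74734 in control 2. Only control 1 stood apart, so the shift with SRPBM scaling gives no evidence of a general fall of circRNAs with IL-1β.

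The next question was which single circRNAs changed with IL-1β. Of 15333 circRNAs with at least 20 reads over the libraries, 3 passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 1 higher and 2 lower. At an unadjusted p under 0.05 there were 528 (3.44%). In the 2-fold and 4-fold simulations 5.72% and 5.84% of unchanged circRNAs had such a p, so 528 was no excess over all tested circRNAs. With a filter of 200 reads, chosen after seeing the data, the share was 8.29% of 3100 circRNAs. No simulation was run at that filter, so an excess among deeply read circRNAs stays open. DESeq2 gave 106 of the 15333 at an adjusted p under 0.05. The 3 past edgeR's test came from 2 genes, the zinc finger gene Zfp292 and Ttc28. In Zfp292, circRNA.27295 (chromosome 4, 34839332 to 34848032, minus strand) had 518 and 445 reads with IL-1β and 0 in both controls, which is at least 204-fold higher (adjusted p = 0.0263). In the same gene, circRNA.27296 (chromosome 4, 34839332 to 34848035) had 0 reads in both IL-1β libraries and 572 and 736 in the controls, at least 171-fold lower (adjusted p = 0.0263). These Zfp292 junctions share 1 end and differ by 3 nt at the other. In Ttc28, circRNA.28572 (chromosome 5, 111182928 to 111183431) had 0 reads with IL-1β against 848 and 1502, at least 307-fold lower (adjusted p = 0.0281). Its neighbour circRNA.28570, whose start lies 4 nt away, had 1292 and 1088 reads with IL-1β and 819 and 1124 in control. Bounds use a floor of 3 reads per library.

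With junctions within 5 nt of each other summed, an alternative chosen after seeing the data, 0 circRNAs passed edgeR's test. At an unadjusted p under 0.05 there were 536 (3.52%), or 8.4% of 3085 with a filter of 200 reads. In DESeq2 95 passed an adjusted 0.05 without that filter. The summed Zfp292 locus had 518 and 445 reads with IL-1β and 572 and 736 in control, a log2 change of -0.09 ± 0.25 (SE), and the summed Ttc28 locus a log2 change of -0.50 ± 0.27 with an adjusted p of 0.894 in edgeR. On simulated circRNA counts with 4-fold changes, 64.8% of DESeq2's calls and 34.8% of edgeR's were false. With 2-fold changes DESeq2 made 12 calls and edgeR 1, and all were false. These shares depend on the 200 circRNAs set to change and do not estimate the false share among the 95.

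**Figure D2:**
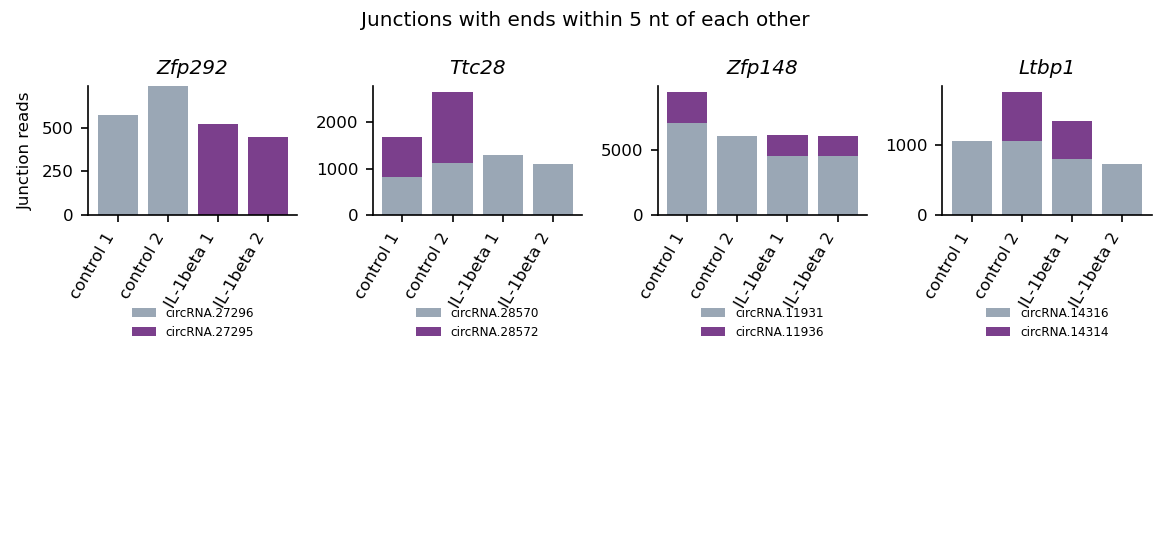
Junction reads (y axis, counts) are stacked for pairs of circRNAs whose ends lie within 5 nt of each other, in each of the 4 libraries (x axis), for Zfp292, Ttc28, Zfp148 and Ltbp1. In Zfp292 and Ttc28 the purple junction follows the groups, while in Zfp148 it has 0 reads in control 2 alone and in Ltbp1 it has 0 reads in control 1 and IL-1β 2.

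Among the remaining circRNAs with the lowest p in that test, all with an adjusted p of 0.886 and named to fill the list to 12 in each direction, values were higher with IL-1β for several circles with reads in every library. The main circle of Bcat1 (circRNA.31933, chromosome 6, 145032783 to 145039635), a cytosolic branched-chain aminotransferase, stood at 2270 ± 222 CPM with IL-1β and 1030 ± 182 CPM in control (n = 2 each). The main circle of Ripk2 (circRNA.27130, chromosome 4, 16151917 to 16158430), a kinase that relays NOD receptor signals to NF-κB, stood at 952 ± 255 and 339 ± 107 CPM. The circle circRNA.20767 of the kinetochore gene Knl1 (chromosome 2, 119076936 to 119086650) stood at 123 ± 48.8 and 24.0 ± 7.27 CPM. Values were also higher for circRNA.39069 of Dpy19l1 at 100 ± 8.72 and 9.95 ± 5.60, circRNA.8374 of Farp1 at 234 ± 31.1 and 81.7 ± 17.5, circRNA.18534 of Ube2w at 458 ± 15.9 and 211 ± 31.5, and circRNA.31058 of Mthfd2l at 82.2 ± 0.313 and 12.4 ± 6.71. Circles of Hpcal1 (circRNA.5718), Atp6v1c1 (circRNA.10161), Msrb3 (circRNA.286) and Zfp148 (circRNA.11938) had 0 reads in both controls, at least 27.6-, 29.0-, 17.6- and 17.4-fold below their IL-1β levels.

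Values were lower with IL-1β for abundant circles of Asph, Tasp1, Setbp1 and Tenm4, again without passing edgeR's test (adjusted p = 0.886 for each). The main circle of Asph (circRNA.28180, chromosome 4, 9508627 to 9532065), aspartate β-hydroxylase, stood at 2630 ± 248 CPM with IL-1β and 4570 ± 195 CPM in control (n = 2 each). For circRNA.21452 of Tasp1 (chromosome 2, 140008699 to 140057499), a protease, the values were 1530 ± 41.9 and 2670 ± 86.8 CPM. For circRNA.15854 of Setbp1 (chromosome 18, 79075394 to 79087180) they were 451 ± 51.5 and 891 ± 12.2 CPM, and for circRNA.35849 of the teneurin gene Tenm4 (chromosome 7, 96735685 to 96778019) 97.3 ± 31.9 and 368 ± 48.1 CPM. The Srpx circle circRNA.40589 stood at 67.0 ± 6.31 and 181 ± 12.6 CPM, and circRNA.40577, on an unplaced scaffold and without a host gene, at 26.2 ± 9.55 and 114 ± 12.4. Circles of Atl2 (circRNA.14427), Ccdc91 (circRNA.32022), Sfi1 (circRNA.3273) and Slc8a1 (circRNA.14503) had 0 reads in both IL-1β libraries, at least 27.1-, 21.2-, 17.1- and 13.2-fold below control. All 24 circRNAs named as higher or lower passed an adjusted p of 0.05 in DESeq2. They were picked for a low edgeR p on the same counts, so this adds no independent support.

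The third question was whether genes differed in their circRNA output, the junction reads summed over all circles of a host, which does not depend on how reads are divided between near-identical junctions of a gene. Nfkb1, which encodes the p105 precursor and p50 subunit of NF-κB, gave 4730 ± 633 CPM with IL-1β and 2240 ± 403 in control, 2.11-fold higher. All 4 of its tested circles were higher, and 1 of its circles held 80.3% of its reads. A single circle held 98.1% of the Ripk2 reads and 90.2% of the Bcat1 reads, so these hosts largely repeat the circles named above. Ripk2 gave 979 ± 270 and 357 ± 106 CPM, 2.74-fold higher, and Bcat1 2500 ± 253 and 1220 ± 96.0 CPM, 2.05-fold higher. Tenm4 gave 683 ± 61.8 CPM with IL-1β and 1720 ± 432 in control, 2.53-fold lower, with all 22 of its tested circles lower. Utrn gave 9210 ± 316 and 14200 ± 401 CPM, 1.54-fold lower, with 33 of 46 tested circles lower and 13 higher (n = 2 in each group throughout). None of the 4879 tested hosts passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.576. At an unadjusted p under 0.05 there were 222 (4.55%), 102 of them higher. In the 2-fold and 4-fold simulations 4.39% and 5.28% of unchanged hosts had such a p, so 222 was no clear excess over all tested hosts. With a filter of 50 reads the share was 5.35%, and with 200 reads 7.42% of 2209 hosts. No simulation was run at those filters, so an excess among deeply read hosts stays open. Of the 4879 hosts DESeq2 gave 55, 29 higher and 26 lower, all 20 named here among them. The 20 were picked for a low edgeR p on the same counts, so this adds no independent support. On simulated host counts with 4-fold changes in 200 hosts 20.2% of DESeq2's calls were false, which does not estimate the false share among the 55. At that simulated size edgeR recovered 36.5% of changed hosts, 74.5% of those with at least 200 reads, and at 2-fold it recovered 0%.

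**Figure D3:**
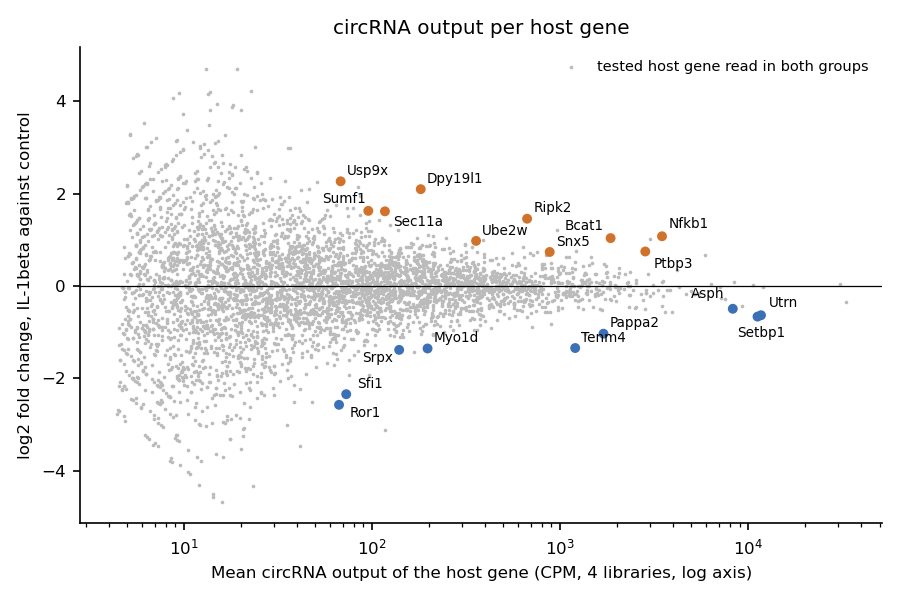
Log2 fold change of circRNA output with IL-1β against control (y axis) is plotted against mean output over the 4 libraries (x axis, CPM, log axis) for tested host genes read in both groups (grey). Named hosts are in orange (higher) and blue (lower), and none passed edgeR's test, where the smallest adjusted p was 0.576.

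Of the other hosts with the lowest p on the higher side, none past the threshold, Ptbp3, an RNA-binding protein of the polypyrimidine tract-binding family, gave 3570 ± 281 CPM with IL-1β and 2110 ± 101 in control. The deubiquitinase gene Usp9x gave 113 ± 28.1 and 23.3 ± 5.72 CPM, and Dpy19l1, a C-mannosyltransferase of the endoplasmic reticulum, 295 ± 3.86 and 68.5 ± 36.1. Sec11a, a signal peptidase subunit, gave 177 ± 12.5 and 57.4 ± 9.41 CPM, Ube2w, a ubiquitin-conjugating enzyme, 475 ± 29.3 and 241 ± 28.3, Sumf1, which activates sulfatases, 145 ± 10.4 and 46.7 ± 4.47, and the sorting nexin Snx5 1100 ± 62.3 and 657 ± 0.957. On the lower side, Asph gave 6900 ± 112 and 9680 ± 440 CPM, Setbp1 8690 ± 915 and 13700 ± 3280, and Pappa2, a protease of insulin-like growth factor binding proteins, 1120 ± 4.25 and 2290 ± 966. The receptor gene Ror1 gave 19.1 ± 8.08 and 114 ± 32.9 CPM, Sfi1 24.0 ± 7.06 and 122 ± 5.25, the myosin gene Myo1d 111 ± 15.3 and 284 ± 93.6, and Srpx 77.5 ± 10.2 and 202 ± 30.4. Atl2, an atlastin, had 0 reads in both IL-1β libraries and 67 and 141 in control, at least 28.0-fold lower. In several of these hosts 1 circle held most reads: 98.0% in Ror1, 94.9% in Ube2w, 91.6% in Srpx, 88.9% in Ptbp3 and 86.4% in Setbp1. In others the share was lower, such as 26.6% in Usp9x and 21.7% in Myo1d.

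**Figure D4:**
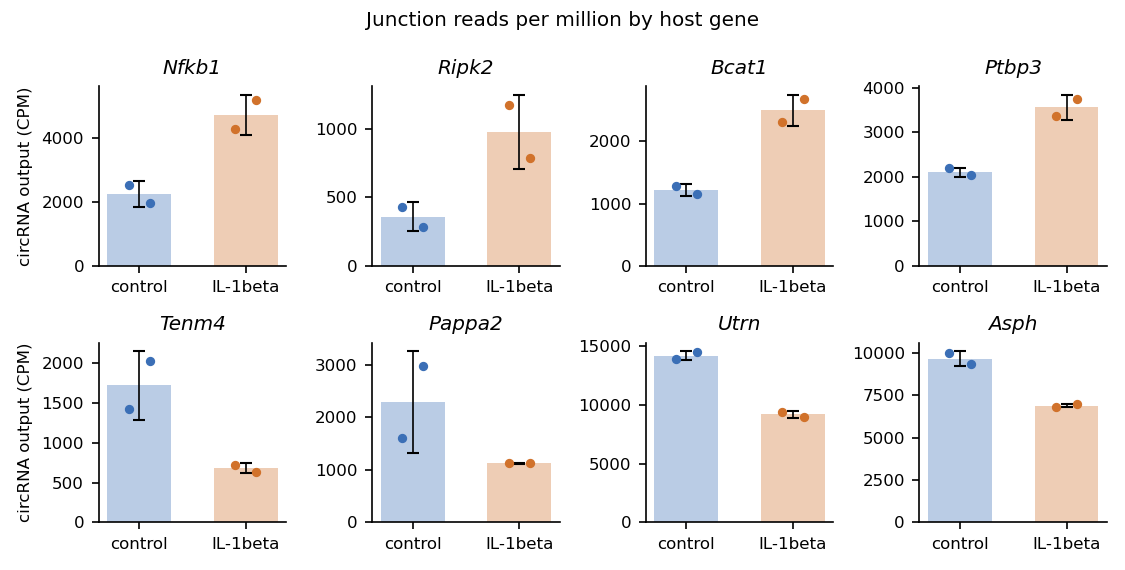
circRNA output (y axis, CPM from 0) of 8 host genes is shown as group means (bars), SD (error bars, n = 2) and single libraries (points), with control in blue and IL-1β in orange. For Nfkb1, Ripk2, Bcat1 and Ptbp3 both IL-1β libraries lie above both controls, and for Tenm4, Pappa2, Utrn and Asph both lie below.

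Gene lists fixed before the data were examined were tested on host output with camera, which compares the members of a list with the other hosts. Hosts of the cell cycle and DNA replication list were higher with IL-1β as a group: 35 of 51 tested members had a positive log2 change, with a median of 0.49 (adjusted p = 0.032 over 13 lists, camera in limma). With an estimated correlation the adjusted p was 0.698, and with 1 library left out the median was 0.28 to 0.58 and the adjusted p 0.012 to 0.276. Of its 4 members with the lowest p, none passed over all hosts or adjusted over the list alone. Knl1 gave 178 ± 33.1 and 71.1 ± 24.5 CPM, the DNA polymerase α gene Pola1 394 ± 11.3 and 237 ± 3.45, and the helicase gene Hells 53.7 ± 1.37 and 14.8 ± 7.59 (IL-1β and control, n = 2 each). The mitotic kinase gene Cdk1 went the other way, with 0 reads in both IL-1β libraries and 27 and 19 in control, at least 6.16-fold lower. The median stayed at 0.49 with the 2 members that had a group at 0 set to their bound, a change that could hardly move a median.

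Hosts of the fibroblast matrix list were lower as a group: 15 of 18 tested members had a negative log2 change, with a median of -0.47 (adjusted p = 0.035, camera in limma), and the adjusted p was 0.768 with an estimated correlation. Without control replicate 2 the median was -0.08, and with 1 library left out the adjusted p ranged from 0.016 to 0.809. None of its members passed over all hosts or adjusted over the list alone. The collagen genes Col12a1, Col6a3 and Col5a2 gave 248 ± 29.1, 8.64 ± 1.98 and 30.5 ± 2.15 CPM with IL-1β and 479 ± 155, 44.9 ± 12.7 and 72.9 ± 24.5 CPM in control, and Thbs2 (thrombospondin) had 0 reads with IL-1β and 9 and 27 in control, at least 4.86-fold lower. The median was -0.47 with Thbs2 at its bound, which also lies below the median and so could not move it.

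Hosts of the NF-κB and inflammatory response list had positive log2 changes in 16 of 25 tested members, with a median of 0.39, and the list did not pass (adjusted p = 0.138, camera in limma). The list holds 67 genes, and Il6, Ptgs2, Nos2, Lcn2, Cxcl1 and Ccl2 were among those with too few junction reads to test. Nfkb1 and Ripk2 were the 2 members that passed adjusted over the list alone, and 0 passed over all hosts (2 with the replicate block). With that block Traf3, which was lower with IL-1β, also passed adjusted over the list alone. Its circle circRNA.5492 had 0 reads in IL-1β 2 alone. Adjusted over the list alone, Ripk2 did not pass without IL-1β 1 or without control 2, and Nfkb1 did not pass without IL-1β 2. The receptor for IL-1 itself, Il1r1, had 15 and 14 reads from 1 circle with IL-1β and 0 in both controls. The zinc transporter gene Slc39a14 had 6 and 20 against 0 (adjusted p = 0.882 in edgeR for each). Against 3 reads per library these are at least 6.01-fold and 5.27-fold, by counting error only. At this depth a 0 was common: of circRNAs with 10 to 19 reads in IL-1β 1, 48.35% had 0 in IL-1β 2 and 47.37% in control 1. Hosts of the interferon response list had negative log2 changes in 9 of 10 tested members, with a median of -0.79 (adjusted p = 0.138), and -1.47 to -0.40 with 1 library left out. Among them were Irf2 at 134 ± 11.7 and 185 ± 13.3 CPM, Stat2 at 84.9 ± 55.4 and 130 ± 18.6, Trim25 at 8.60 ± 0.463 and 25 ± 11.8, and Znfx1 at 1.67 ± 2.37 and 10.4 ± 3.85.

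No other list passed camera, and none of their members passed over all hosts or adjusted over a list alone in edgeR's main test. Of the members named, Ror1, Fgfr2, Phex and Upf2 passed over all hosts in DESeq2 (adjusted p = 0.00134, 0.0274, 0.0403 and 0.0453). Members did pass in other settings: Ror1 (lower) and Rhobtb3 (higher) over all hosts with the replicate block, Ror1 over its list with a filter of 200 reads, and Fgfr2, Map3k4, Rasa2, Nfix and Rhobtb3 over a list alone without control 1, Nfix of these also over all hosts. RNA-binding and circRNA biogenesis factors had a median of 0.26 over 35 hosts (adjusted p = 0.16). It was -0.08 without control 2 and 0.52 without control 1, where the list passed (adjusted p 0.036 to 0.9 with 1 library left out, camera in limma). Members were Upf2 at 287 ± 72.3 and 136 ± 11.1 CPM, Rbm39 at 138 ± 12.3 and 68.5 ± 34.9, Ago3 at 76.8 ± 1.85 and 134 ± 36.8, and Celf1 at 150 ± 0.496 and 95.5 ± 5.09. Actin and focal adhesion genes had a median of -0.19 over 49 hosts (adjusted p = 0.524). Their 4 lowest-p members were Pxn at 14.5 ± 0.0207 and 68.6 ± 25.6 CPM, Itga8 at 29.3 ± 12.2 and 96.0 ± 3.25, Vcl at 84.1 ± 3.82 and 178 ± 15.3, and Palld at 133 ± 1.82 and 243 ± 19.1. Fry's test for change in either direction (in limma) gave adjusted p = 0.0129 for that list and 0.00579 for the cell cycle list, and its test for 1 direction passed for no list. Neither passed with the replicate block (adjusted p = 0.379 for each), with 1 value per circRNA (0.167 and 0.16) or with any library left out (0.108 to 0.83 and 0.116 to 0.83), and both passed with a filter of 200 reads (0.0373 for each). MAPK and PI3K genes had a median of -0.13 over 41 hosts (adjusted p = 0.779), with Fgfr2 at 2910 ± 18.0 and 4310 ± 613 CPM, Map2k5 at 480 ± 32.6 and 309 ± 18.8, and Rasa2 at 1300 ± 76.0 and 843 ± 242.

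Wnt genes had a median of 0.11 over 26 hosts (adjusted p = 0.792), TGF-β and BMP genes 0.03 over 25 (adjusted p = 0.64), chromatin regulators -0.08 over 66 (adjusted p = 0.792), recurrent circRNA hosts -0.02 over 50 (adjusted p = 0.779), hypertrophy and bone genes -0.08 over 12 (adjusted p = 0.792), and matrix proteases -0.01 over 12 (adjusted p = 0.913), by camera in limma. Only 12 of 35 listed proteases and inhibitors could be tested, and Mmp3, Mmp9, Mmp13, Adamts4 and Adamts5 were not among them. The mean differed in sign from the median for the TGF-β list (-0.12), the recurrent hosts (0.04), the hypertrophy list (0.06) and the proteases (0.04), and camera gave the direction of the mean for the last 3 and of the median for TGF-β. Examples were Ror1 and Lrp5 (407 ± 61.4 and 549 ± 61.4 CPM) for Wnt, Tgfb2 (57.1 ± 28.1 and 11.6 ± 6.53) and Tgfbr1 (103 ± 9.65 and 48.9 ± 2.22) for TGF-β. Others were Ep300 (238 ± 95.5 and 459 ± 47.8) and Crebbp (698 ± 23.1 and 492 ± 33.8) for chromatin, Crim1 (2010 ± 146 and 1490 ± 40.9) and Camsap1 (2350 ± 122 and 1780 ± 414) for recurrent hosts, Phex (139 ± 15.8 and 52.4 ± 8.85) for bone, and Adam17 (456 ± 26.0 and 271 ± 44.3) and Ctsk (57.3 ± 25.8 and 129 ± 57.7) for proteases. In Ep300, circRNA.10808 held 52.1% of the host's reads and had 0 in IL-1β 2 alone, and the log2 change of Ep300 was -1.43 to -0.59 with 1 library left out.

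**Figure D5:**
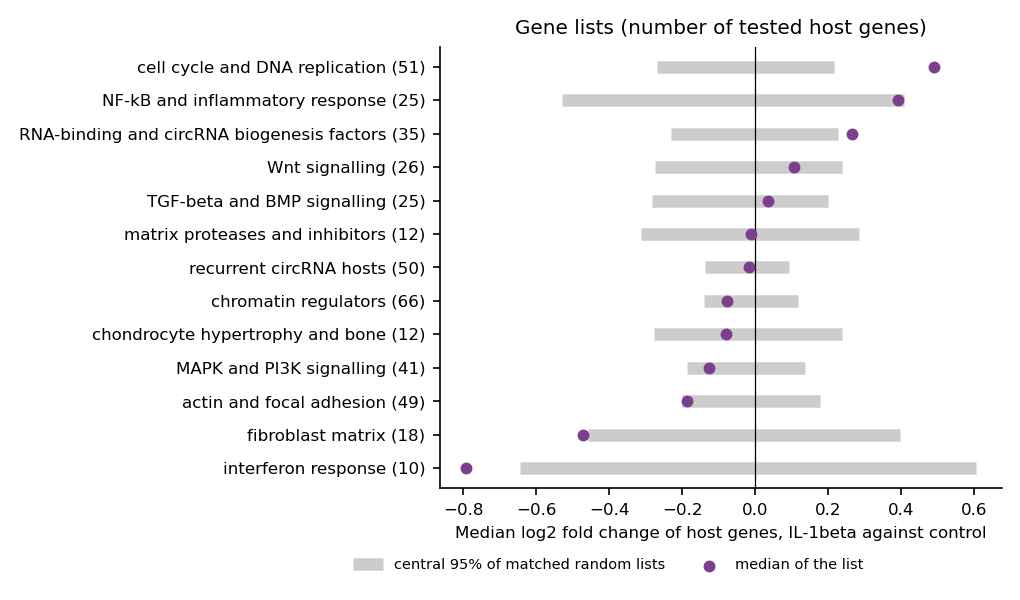
The median log2 fold change of host circRNA output with IL-1β against control (x axis) is shown for 13 gene lists (points; number of tested hosts in parentheses) over the central 95% of 10000 random lists matched on size and mean level (grey bars). The medians of 4 lists lie outside their bars, cell cycle (0.49) and RNA-binding factors (0.26) above and interferon response (-0.79) and fibroblast matrix (-0.47) below.

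Cartilage matrix genes gave few circRNAs: 4 of 25 listed genes could be tested, too few for a list test on hosts. With 1 value per circRNA, 10 of 14 cartilage circles had a negative log2 change, with a median of -0.63 (adjusted p = 0.196 over 17 lists, camera in limma). Sox6 gave 67.0 ± 1.71 CPM with IL-1β and 108 ± 27.5 in control, Matn2 34.8 ± 15.5 and 60.1 ± 6.92, Bgn 21.3 ± 4.92 and 27.6 ± 14.2, and Sox5 232 ± 38.3 and 216 ± 96.0 (n = 2 each). Markers of other cell types were sparse too, as the cartilage genes were, so their small number is no measure of how few such cells there were. Macrophage and leukocyte markers gave 2 tested hosts, Mertk at 29.1 ± 14.4 and 44.7 ± 16.1 CPM and Mrc1 at 9.15 ± 1.25 and 6.41 ± 9.06. The endothelial marker Flt1 stood at 132 ± 20 and 111 ± 16.6 CPM, and the muscle marker Myom1 had 0 reads with IL-1β and 3 and 23 in control. Synovial fibroblast markers gave Cdh11 at 261 ± 63.4 and 370 ± 32.0 CPM, Pdgfra at 29.2 ± 11.3 and 52.2 ± 13.2, and Htra4 at 3.10 ± 4.39 and 11.7 ± 2.86, all lower with IL-1β in the mean, as was the median of the fibroblast matrix hosts. With 1 value per circRNA, 7 of 9 synovial fibroblast circles had a negative log2 change, with a median of -1.44 (adjusted p = 0.196), and the adipocyte and endothelial lists did not pass either (adjusted p = 0.746 and 0.92, camera in limma). Adipocyte markers gave Ghr at 280 ± 117 and 259 ± 98.3 CPM and Acsl1 at 23.1 ± 18.5 and 29.1 ± 41.1. None of these hosts passed edgeR's test.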

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

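Sums over junctions within 5 nt, the filter of 200 reads and robust empirical Bayes were chosen after seeing the data. The count of 3 circRNAs was 61 with the replicate block, 106 with DESeq2 (adjusted p NA for 6540), 61 with no low-count filter, 0 with a filter of 50 reads, 0 with merged junctions, 0 with merged junctions and a filter of 200 reads, 95 with merged junctions in DESeq2, and 0 to 4 with 1 library left out. It was 0 without either IL-1β library, 4 without control 1 and 1 without control 2, with 0 of the 3 shared by any of these. RLE, totals, annotated circles, robust fitting and the filter of 200 reads kept all 3, and SRPBM depth kept 2. Of the 106 DESeq2 calls 47 had a group at 0 reads. The host count of 0 was 20 with the block, 55 with DESeq2 (NA for 1041), 12 with no filter and 0 to 2 with 1 library left out, being 1 without IL-1β 1, 2 without control 1 and 1 without control 2. The replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.001 over circRNAs and 0.027 over hosts. A lone library was assumed to vary like the other group. The cause of these changes was not tested, except that merging removes the split between junctions.

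The count of 2 lists past camera was 0 with an estimated correlation, 0 with the block, 0 with 1 value per circRNA, 3 with the filter of 200 reads and 0 to 2 with 1 library left out. The cell cycle median was 0.49 with an estimated correlation, 0.56 with the block (adjusted p = 0.056) and 0.27 per circRNA (0.196), and 0.28 to 0.58 with 1 library left out (0.012 to 0.276). The fibroblast matrix median was -0.47, -0.63 (0.069) and -0.42 (0.196) in turn, and -1.05 to -0.08 with 1 library left out (0.016 to 0.809). The NF-κB median rose to 0.61 at 200 reads (adjusted p = 0.036, camera in limma, 6 hosts). With 1 library left out, medians ranged over 0.24 to 0.64 for NF-κB (0.078 to 0.851), -1.47 to -0.40 for interferon (0.152 to 0.601), -0.07 to 0.03 for hypertrophy and bone, -0.11 to 0.03 for chromatin, -0.17 to 0.05 for MAPK and PI3K, -0.06 to 0.16 for proteases, -0.03 to 0.06 for recurrent hosts, -0.08 to 0.52 for RNA-binding factors (past camera without control 1, adjusted p = 0.036), -0.01 to 0.21 for TGF-β and -0.08 to 0.02 for Wnt. The Wnt median was -0.01 at 200 reads and the protease median 0.00 per circRNA. The mean number of circRNAs per library was 16609 at 5 reads, and 18895 and 18872 at 2 reads and after thinning. The setting of 2 reads could hardly move it, since almost no circRNA had exactly 1 read in a library. The cause of the changes in this paragraph was not tested.

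Of 110 named circRNAs and hosts, 100 kept their direction under every setting run and 10 did not. Most were picked for a low p on the same counts, so the 100 are no independent support. Where the libraries of the groups do not overlap, leaving 1 out can hardly reverse the direction. All 10 that reversed had overlapping groups. Of 1394 alternative values 1249 kept direction and side, 106 became significant, 19 ceased to be and 20 reversed. With 1 library left out, log2 changes ranged over -0.42 to 0.10 for circRNA.37871, -0.13 to 0.14 for circRNA.20556, -0.05 to 0.08 for circRNA.37633, -0.26 to 0.01 for circRNA.17136, -0.81 to 0.32 for Bgn, -0.29 to 0.69 for Sox5, -0.51 to 0.08 for Adam12, -0.48 to 0.64 for Mrc1, -0.39 to 0.61 for Ghr and -1.52 to 7.55 for Acsl1, where 7.55 is a fitted value against 0 control reads and no bound. SRPBM depth gave -0.20 for circRNA.20556 and -0.19 for circRNA.37633. For circRNA.20556 annotated circles gave -0.01, the filter of 200 reads -0.00 and the same filter on merged junctions -0.00. The block gave 1.23 for Acsl1. The cause was not tested.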

Other observations

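The main edgeR test and the list tests with a preset or an estimated correlation were planned. Every other test in this part was chosen or revised after results were seen. The centring of the length trend was corrected after a first run, which took the share kept in the fibroblast matrix list across its bound, so that verdict rests on the correction. By the rules first written, the splice-site switch and the shared change of hosts with IL-1β would have been argued against, but those rules set no error on the values compared.

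Several abundant circles were at 0 reads in 1 library while read deeply in the other 3. The Gigyf2 circle circRNA.20203 (chromosome 1, 87364104 to 87380008) had 5691 and 7137 reads with IL-1β and 9526 in control 2, and 0 in control 1. The Rad52 circle circRNA.31523 (chromosome 6, 119920110 to 119921028) had 2781, 3736 and 3206 reads and 0 in control 2, and the Spopl circle circRNA.22469 1247, 1219 and 691 and 0 in IL-1β 2. There were 30 such circles with at least 50 reads in each of the other libraries, out of 2637 with 50 reads in 3 or more, and 5 of them had reads at a junction within 5 nt in the library at 0.

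The 3 circRNAs past edgeR's threshold all had another junction within 5 nt, as did 336 of 15333 tested circRNAs (2.19%). A candidate explanation is that reads of 1 junction were placed at 2 nearby coordinates: after summing such junctions 0 of the called loci stayed past the threshold, but the Zfp292 junctions are mirror images, so summing had to cancel them and a switch of splice site would give the same. Of 33 near-identical pairs with at least 100 reads at each junction, 23 had a junction used in some libraries and at 0 in others, and in 21 of these it separated libraries of the same group. For a switch with IL-1β, of 8 loci with a junction used in 2 libraries and at 0 in the other 2, 25% followed the groups (exact 95% interval 3.2% to 65.1%), against 33.3% by chance. Placement and a switch cannot be told apart for Zfp292 and Ttc28 from so few loci, and the reads spanning these junctions were not used here.

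The circRNAs read in 1 library only made up 58.55% of the total. Sampling of independent reads from a common level is argued against as the whole cause, since it would put 1.48% of circRNAs in 1 library. Presence that follows IL-1β is argued against too, since circRNAs read in exactly 2 libraries fell in same-group pairs 1.06 times as often as in mixed pairs. Several reads per captured molecule, as amplification gives, may contribute: the most common read number per detected circRNA was 5, 5, 6 and 11 in the 4 libraries, the lowest being 5. Sampling of such molecules from a common level, and joint scoring in the circRNA caller, were not tested and stay open. A minimum near 2 reads is visible. Exactly 1 read was held by 1, 3, 2 and 1 circRNAs in IL-1β 1, IL-1β 2, control 1 and control 2. Exactly 2 reads were held by 606, 693, 774 and 349. How far such a minimum accounts for the 58.55% was not tested.

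By camera at a preset correlation, cell cycle hosts were higher and fibroblast matrix hosts lower with IL-1β, and neither list passed with an estimated correlation (adjusted p = 0.698 and 0.768, camera in limma). Host gene length is argued against as the cause, since 100.9% of the cell cycle median and 94.4% of the fibroblast matrix median stayed after a linear length trend was removed. A shift of the lists with IL-1β is not decided: both medians (2 of 2) lay outside the central 95% of 10000 matched random lists, but these lists were picked for their shift, and of all 13 lists 4 lay outside, with interferon response (percentile 0.82) further out than fibroblast matrix (2.2). Differences between libraries of the same group cannot be told apart from IL-1β for either list: the shifts were 1.94 and 1.38 times the largest within-group difference of the median, and neither call held with an estimated correlation. With 2 libraries per group this stays open, as does a difference in the share of dividing or fibroblast-like cells.

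Circles of the same host changed together. Over 2046 circRNAs with at least 200 reads from 635 hosts, the mean product of same-host changes was 0.0628 squared log2 units with IL-1β against control, above every one of 10000 shuffles of host labels (permutation p = 0.0001, the smallest they can give). The other 2 ways to split the 4 libraries into pairs gave 0.0348 and 0.0311, also beyond shuffled hosts (permutation p = 0.0002 and 0.0009). Within groups, with values scaled to the same spread, the product was 0.0654 between the controls (permutation p = 0.0001) and 0.0005 between the IL-1β libraries (permutation p = 0.44), so shared variation apart from IL-1β was seen in the control pair only. The other 2 splits are built from these same within-group differences, so their p-values are no separate evidence. The hypothesis of a further shared change of hosts with IL-1β was not decided. The difference from the larger of the other 2 splits (0.0348) was 0.028 (bootstrap 95% interval -0.0145 to 0.0559). With 3 splits the smallest exact p is 0.333.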
